A study of Rattus norvegicus with 119 samples.

How the data were processed

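The series measured microRNAs (miRNAs) in the urothelium, the epithelial lining of the bladder, of Sprague-Dawley rats. Per the labels, animals were dosed by mouth every day with vehicle (0.5% methylcellulose), rosiglitazone (10 mg/kg) or pioglitazone in a low (16 mg/kg) and a high (63 mg/kg) dose. Both drugs are thiazolidinediones, agonists of the nuclear receptor PPAR gamma. Rats of both sexes were killed after 3, 28 or 90 days, the urothelium was scraped off the bladder wall and frozen, and Cy3-labelled RNA was hybridised to 1-colour Agilent miRNA arrays. Per the labels, 10 rats of each sex were dosed per group and urothelium of 5 of them was profiled, so each array is a separate animal. The labels and protocols give the low pioglitazone dose as 16 mg/kg/day, which is used throughout, whereas the series' design text gives 13.

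The deposited table holds log2 values for 301 rat miRNAs on 119 arrays. Its background correction, summary of probes and filter on miRNAs are not given in the sources used here. The submitters' processing notes name RMA and limma without versions. Array medians ran from 3.70 to 5.66, so the table as deposited does not have equal quantiles. No detection calls came with the table, and many miRNAs lay close to a floor near the lowest values (the minimum was 2.69), where a difference is compressed. The number of arrays and this floor limit the precision. No miRNA's level was set against another miRNA's. Names were kept as on the array. Of these names, 275 matched 1 rat RefSeq gene, 23 matched several and 3 matched none. No genome positions were used.

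The 24 groups were the 4 treatments by 2 sexes by 3 times, with 5 arrays each except 1 group of 4 (pioglitazone 16, males, day 28). The labels mark 3 arrays as failing quality control: replicate 2 of the vehicle males at day 28, and replicates 1 and 5 of the females given pioglitazone 16 for 28 days. They were left out, which left 116 arrays, with n = 4 and n = 3 in those groups. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.995.

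All comparisons used limma 3.58.1 in R 4.3.3 on the log2 values, with 1 mean per group over all 24 groups and moderated variances (92 residual and 2.33 prior degrees of freedom, median standard deviation 0.85). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of 33 contrasts over the 301 miRNAs, with a threshold of 0.05. These contrasts were 18 comparisons of a treated group with the vehicle group of its sex and time, the mean of each treatment's 6 comparisons, differences between treatments, differences of each effect between sexes and between days 90 and 3, and sex and time contrasts among vehicle rats. Log2 differences are given with standard errors (SE). Each SE rests on 1 moderated variance per miRNA over all 24 groups, not on the spread of the compared groups alone. An unadjusted count is the number of miRNAs with an unadjusted limma p under 0.05. Without any difference a share of about 0.05 of the 301 miRNAs would lie under this limit. Counts near or below that share therefore show no effect.

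The design, the first set of alternatives below, the rule for named miRNAs and the miRNA lists were fixed before the data were examined. For each mean over the 6 sex and time combinations, the named miRNAs were up to 10 higher and 10 lower past the threshold with the largest differences, among those with the same direction in at least 5 of the 6. For every other contrast they were up to 3 higher and 3 lower past the threshold, or, where none passed, the 2 with the smallest p, given as values. Members of a list could be named as its examples. Both strands of a hairpin counted, and an asterisk marks the strand the array's annotation calls minor.

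The lists and their measured members were epithelial miRNAs (13), muscle (8), fibroblast and mesenchymal (9), the imprinted Dlk1-Dio3 cluster (27), endothelial (2), red blood cell (3), leukocyte (5), inflammation and injury response (10), neural (3), the miR-17-92 cluster and its paralogs (13), p53-responsive (7), adipocyte differentiation (19), miRNAs described to target Pparg (4), the let-7 family (13), the miR-29 family (5), hypoxia (1) and liver, of which 0 were measured. The muscle and fibroblast lists share miR-143, miR-143* and miR-145. Lists of at least 3 members were tested against the other miRNAs with camera in limma at its preset correlation of 0.01, in 42 tests adjusted together. The same tests with an estimated correlation, and fry, which asks whether a list moves one way, were run beside it. Values of fry are given only for the Dlk1-Dio3 and miR-29 lists, and not for every test. List tests chosen after the values were seen were adjusted within their own sets, so adjusted p-values of different sets are not on the same footing.

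The alternatives fixed then were to keep the failed arrays, centre each array on its median, use only the brighter miRNAs (mean above the median miRNA), fit only the groups of a contrast, block on the replicate number, estimate the correlation within lists, leave out each array in turn, and split the vehicle arrays for the overlap between compounds. Chosen after seeing the data were the contrasts without the male day-28 groups, the same with those arrays also out of the fit, quantile normalization, the array median or a list mean as a covariate, list tests in vehicle rats, and day 90 against day 3 in treated rats. For each contrast, up to 100 assignments of the same arrays to its groups were fitted, the real one included. For the overlap, 100 sets of unchanged groups were simulated, with residual arrays of all groups drawn for vehicle and treated groups alike.

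The fit was tested on simulated data with 60 of 301 miRNAs changed, in 20 draws. For rosiglitazone in females at day 90 it recovered 33.0% of 2-fold and 72.3% of 4-fold changes, and 5.67% of its calls were false. For pioglitazone 16 in females at day 28 the shares were 25.7%, 57.0% and 7.81%. For the mean effect of pioglitazone 63 they were 85.5%, 98.0% and 3.00%, and for the sex contrast in vehicle rats 61.5%, 92.8% and 11.6%. The simulation drew residual arrays of all groups alike, so it lacks the unequal spread of the real groups. Its false shares may not hold for them. Correlations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.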

Results

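The arrays measured rat miRNAs in bladder urothelium from rats given vehicle, pioglitazone 16, pioglitazone 63 or rosiglitazone 10 mg/kg/day. Each combination of treatment, sex and time (3, 28 or 90 days) held 5 rats, apart from 3 groups reduced to 3 or 4 arrays. The design asks which urothelial miRNAs 2 related diabetes drugs alter, at which dose, in which sex and after how long. Values are log2 intensities between 2.69 and 16.87, and the median array median was 5.39. In a single comparison of 5 against 5 arrays the median 95% interval reached 1.07 to either side of the log2 difference.

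In females, treated rats differed from vehicle in 2 miRNA calls over 9 comparisons. miR-376b-5p, from the imprinted Dlk1-Dio3 cluster, was higher after 28 days of pioglitazone 16, at 4.56 ± 1.13 (SD, n = 3) against 3.44 ± 0.09 (SD, n = 5). The log2 difference was 1.12 (SE 0.18, adjusted p = 8.48e-06), and 3 of 3 treated arrays lay above every vehicle array. This SE comes from the variance over all 24 groups and does not measure the treated SD of 1.13. miR-328a* was lower after 90 days of pioglitazone 63, at 3.82 ± 0.30 against 4.98 ± 0.86 (SD, n = 5 each). That difference was -1.17 (SE 0.29, adjusted p = 0.0453), and 5 of 5 treated arrays lay below the vehicle mean, 3 of them below every vehicle array. At the same time miR-328a* was 3.91 ± 0.28 with pioglitazone 16 and 4.05 ± 0.52 with rosiglitazone (SD, n = 5 each), which did not pass (adjusted p = 0.130 and 0.318).

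The other 7 female comparisons called 0 miRNAs in limma. With pioglitazone 16 the smallest p belonged to miR-3564 (-1.11) and miR-142-3p (-1.27, a leukocyte miRNA) at day 3, and to miR-328a* (-1.08) and miR-370 (-1.67) at day 90. Unadjusted counts there were 3 and 17. With pioglitazone 63 they were miR-411 (1.21) and miR-341 (0.91) at day 3, and miR-190 (1.37) and miR-29a* (0.74) at day 28, with unadjusted counts of 11 and 8. For rosiglitazone they were miR-136* (1.05) and miR-431 (0.49) at day 3, miR-878 (1.66) and miR-743a (1.76) at day 28, and miR-365 (1.24) and miR-328a* (-0.93) at day 90. Unadjusted counts with rosiglitazone were 16, 38 and 12. miR-878 and miR-743a passed at adjusted p = 0.0414 each when the male day-28 arrays were out of the fit. The calls for miR-376b-5p and miR-328a* ended with arrays centred on their median and with only the groups of the contrast (0 calls in each), and that for miR-376b-5p also with quantile normalization. With the failed arrays kept, pioglitazone 16 gave 20 calls in females at day 28 and pioglitazone 63 gave 0 in females at day 90. With the replicate block the difference in miR-328a* was -1.17 with adjusted p = 0.0533. The call for miR-328a* also ended without vehicle replicate 2 or 3 or pioglitazone 63 replicate 1, 2, 3 or 5.

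In males at day 3, 9 miRNAs were lower and 2 higher with rosiglitazone than with vehicle. The largest differences were in miR-434 (-2.04, SE 0.57, adjusted p = 0.0229), miR-335 (-1.97) and miR-329 (-1.77), and 5 of 5 treated arrays lay below the vehicle mean for each, with 3, 4 and 3 below every vehicle array. miR-3562 (0.79) and miR-598-5p (0.74) were higher, with 5 and 4 of 5 arrays above every vehicle array. miR-434 stood at 4.31 ± 1.14 with rosiglitazone and 6.36 ± 1.36 with vehicle (SD, n = 5 each). It was 4.68 ± 1.52 with pioglitazone 16 and 4.70 ± 1.40 with pioglitazone 63, where 0 miRNAs passed in limma.

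Of the 27 measured miRNAs of the Dlk1-Dio3 cluster, an imprinted locus active in embryonic and mesenchymal tissue, 6 were lower with rosiglitazone in males at day 3 and 0 higher. Adjusted over the list alone, 15 were lower and 1 higher. The list median was -0.87 with rosiglitazone, -0.64 with pioglitazone 16 and -0.53 with pioglitazone 63, negative in all 4 scalings tried (-0.52, -0.36 and -0.46 with centred arrays). With an estimated correlation the adjusted p was 0.0464, 0.0812 and 0.0437, and by fry it was 0.00238, 0.0411 and 0.0449. In females at day 3 the list median was 0.56 with rosiglitazone (adjusted p = 0.0353 with an estimated correlation), 0.17 with pioglitazone 63 (0.344) and -0.19 with pioglitazone 16 (0.153), and the first was 0.08 with centred arrays. By fry the female adjusted p was 0.0226, 0.223 and 0.485 in the same order. These list tests were chosen after the values were seen, and their p-values are adjusted over tests of the Dlk1-Dio3 list alone. Median values of the fibroblast and muscle lists in rosiglitazone males were -1.49 and -0.81, and of the epithelial list 0.74, with 0 members called in each. The fibroblast median was -0.75 with pioglitazone 16 and -0.48 with pioglitazone 63. Red cell medians were -0.81 with rosiglitazone, -0.81 with pioglitazone 16 and -0.79 with pioglitazone 63, again with 0 members called.

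Leaving out replicate 3 of the vehicle males at day 3 took the 11 rosiglitazone calls to 0, and leaving out replicate 2 took them to 21. Centred arrays left 1 call (miR-672, higher by 1.94), quantile normalization left 0, and the array median as a covariate gave 6 higher and 11 lower. The median of all miRNAs went from -0.16 to 0.18 with centred arrays, and in rosiglitazone females at day 3 from 0.17 to -0.31. In the pioglitazone comparisons at day 3 the smallest p belonged to miR-329 (-1.57) and miR-434 (-1.67) for the low dose, and to miR-344a-3p (-1.12) and miR-329 (-1.58) for the high dose. Unadjusted counts were 19 and 14, beside 45 with rosiglitazone.

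In males at day 90, 0 miRNAs passed for any treatment in limma, with unadjusted counts of 22, 14 and 11. miR-181a (-2.30) and miR-222 (-2.42) had the smallest p with pioglitazone 16, miR-181c (-1.80) and miR-144 (-1.85) with pioglitazone 63, and miR-222 (-2.06) and let-7i (-0.53) with rosiglitazone. With the male day-28 arrays out of the fit, miR-181a passed for pioglitazone 16 (adjusted p = 0.0404).

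**Figure D1:**
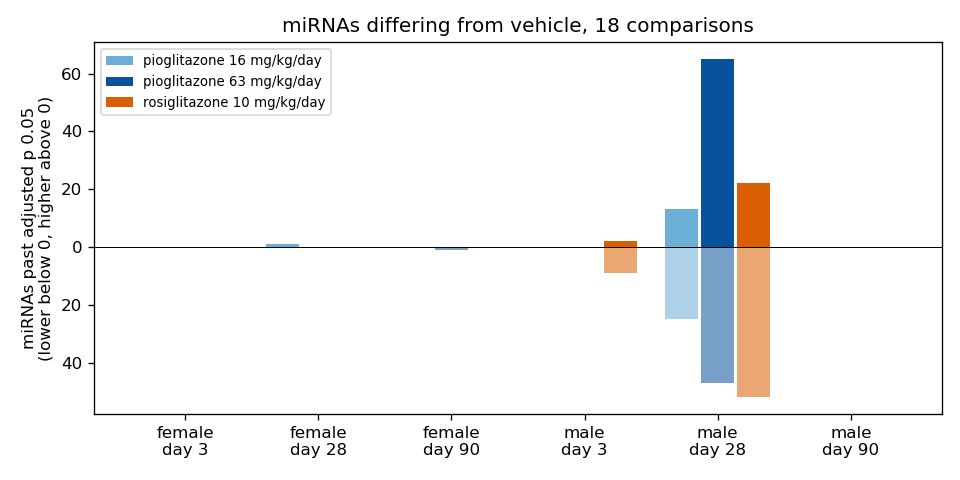
Number of miRNAs past an adjusted p of 0.05 in limma for each treatment against vehicle of the same sex and time (18 comparisons), with higher miRNAs above 0 and lower ones below. Males at day 28 hold 112 calls with pioglitazone 63, 74 with rosiglitazone and 38 with pioglitazone 16, and the other 15 comparisons hold 11, 1, 1 or 0.

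Males at day 28 gave most calls. Against vehicle, 65 miRNAs were higher and 47 lower with pioglitazone 63, 22 higher and 52 lower with rosiglitazone, and 13 higher and 25 lower with pioglitazone 16, with unadjusted counts of 140, 99 and 69. Against their own treatment at days 3 and 90, vehicle males at day 28 differed in 156 miRNAs and pioglitazone 16 males in 74, pioglitazone 63 males in 0 and rosiglitazone males in 1. miR-211, which lies in an intron of the melanocyte gene Trpm1, differed from vehicle by -5.24 (SE 0.72, adjusted p = 1.40e-09) with pioglitazone 63 and by -4.71 (SE 0.72, adjusted p = 3.47e-08) with rosiglitazone. It stood at 9.08 ± 3.96 with vehicle (SD, n = 4) and 8.05 ± 0.78 with pioglitazone 16 (SD, n = 4). With pioglitazone 63 it was 3.84 ± 1.38 and with rosiglitazone 4.37 ± 1.93 (SD, n = 5 each). The SEs and p-values for miR-211 use the variance over all 24 groups. They do not measure the spread of the vehicle arrays, which ran from 3.22 to 11.67. Vehicle rats of the other 5 sex and time combinations had group means between 3.27 and 4.28. The last was in males at day 3 (SD 2.12), where the highest array was 8.07. In pioglitazone 63 females at day 90 the highest array was 7.60.

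The other miRNAs furthest below vehicle with pioglitazone 63 were miR-328b-3p (-5.12) and let-7b* (-5.08), and with rosiglitazone let-7b* (-5.21) and miR-328b-3p (adjusted p = 1.03e-09), with 5 of 5 arrays below the vehicle mean each. Below every vehicle array lay 3, 0 and 2 of 5 pioglitazone 63 arrays for miR-211, miR-328b-3p and let-7b*, and 1, 0 and 1 of 5 rosiglitazone arrays. With pioglitazone 63, miR-322 (4.94, SE 1.32, adjusted p = 0.00175), its relative miR-15b (4.59) and miR-96 (4.43) were higher than in vehicle rats, with 4, 5 and 3 of 5 arrays above every vehicle array. Higher with rosiglitazone than with vehicle were the endothelial miR-126 (3.86, SE 0.80, adjusted p = 4.71e-05), miR-19a of the miR-17-92 cluster (3.16) and the myeloid miR-223 (2.53), with 4 of 5 arrays above every vehicle array for each. With pioglitazone 16, miR-96 (5.33, SE 1.58, adjusted p = 0.0164), miR-19b (4.35) and miR-322 (4.08) were higher, with 4, 3 and 3 of 4 arrays above every vehicle array. Lower were miR-181b (-2.46), miR-298 (-2.09) and the p53-responsive miR-34b* (-2.03), with 2, 0 and 0 of 4 arrays below every vehicle array.

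The list counts below stand beside the calls over all measured miRNAs, 65 higher and 47 lower with pioglitazone 63. A count alone therefore does not set a list apart, and every count rests on the same 4 vehicle arrays. Among the lists, 7 of 13 miRNAs of the proliferation-linked miR-17-92 cluster and its paralogs were higher with pioglitazone 63 than with vehicle (8 adjusted over the list alone, with 1 lower), such as miR-19b (4.32), miR-19a (3.13) and miR-20a (2.27). Their median was 1.68, and it stayed positive in all 4 scalings. With rosiglitazone 2 of them were higher and 1 lower, and with pioglitazone 16 3 were higher. Of 9 fibroblast miRNAs, 4 were higher with pioglitazone 63, among them miR-199a-3p (3.20), miR-214 (2.92) and miR-152 (2.47). Of 10 inflammation miRNAs 4 were higher, including miR-31 (3.69) and miR-146a (3.13). The endothelial miR-126 (3.90), the red cell miRNAs miR-451 (3.62) and miR-144 (1.85), the leukocyte miRNAs miR-142-3p (1.57) and miR-223 (1.80), and the hypoxia-responsive miR-210 (2.14) were also higher.

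Of 13 epithelial miRNAs 2 were higher, miR-96 (4.43) and miR-183 (3.77), and the list median of 0.49 became -0.07 with centred arrays. Of 8 muscle miRNAs 1 was higher (miR-499, 1.36). Members of the let-7 family went both ways with pioglitazone 63: 3 were higher, among them miR-98 (3.21), and 5 minor strands lower, among them let-7f-1* (-3.70). The family median of 0.31 turned to -0.26 with centred arrays. In the adipocyte list 5 of 19 were higher, among them miR-103 (3.76) and miR-107 (3.80), whereas 0 of 4 miRNAs described to target Pparg passed. In the neural list 1 of 3 was higher (miR-7a, 1.89), in the p53 list 1 of 7 lower (miR-34b*, -3.84), and in the miR-29 family 2 of 5 lower, both minor strands (miR-29a*, -1.28, and miR-29c*, -1.62). Of 27 Dlk1-Dio3 miRNAs 8 were lower, such as miR-434 (-1.86) and miR-337 (-1.79), while the list median was -0.11.

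With rosiglitazone, males at day 28 showed 0 calls in the epithelial, muscle, fibroblast, red cell, inflammation and Pparg lists. Of 27 Dlk1-Dio3 miRNAs 8 were lower than in vehicle rats, among them miR-434 (-2.27) and miR-337 (-1.69), and the list median of 0.06 became -0.14 with centred arrays. In the let-7 family 5 minor strands were lower and 2 members higher. With pioglitazone 16, 5 of 27 were lower in the Dlk1-Dio3 list and 1 of 13 higher in the epithelial list (miR-96).

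The 3 male day-28 comparisons share the same 4 vehicle arrays, whose array medians averaged 4.29 ± 0.37 (SD, n = 4), against 5.49 ± 0.18 and 5.31 ± 0.14 (SD, n = 5 each) in vehicle males at days 3 and 90. The median difference over all miRNAs was 0.37 with pioglitazone 63, 0.16 with rosiglitazone and 0.01 with pioglitazone 16, and with centred arrays it was -0.19, -0.03 and -0.60. With pioglitazone 63 the split of calls was 48 higher and 51 lower with centred arrays, with pioglitazone 16 it was 22 and 21 after quantile normalization, and with rosiglitazone it was then 43 and 57, or 37 and 55 with the array median as a covariate. Without vehicle replicate 1, 3, 4 or 5 the 38 pioglitazone 16 calls went to 79, 0, 8 or 1, and without pioglitazone 16 replicate 2 or 3 to 19 or 10, while pioglitazone 63 gave 68 to 136 calls and rosiglitazone 57 to 107 over all left-out arrays. With only the groups of the contrast rosiglitazone and pioglitazone 16 gave 0 calls each and pioglitazone 63 gave 75, and with only the brighter miRNAs rosiglitazone gave 22, pioglitazone 16 gave 10 and pioglitazone 63 gave 72.

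**Figure D2:**
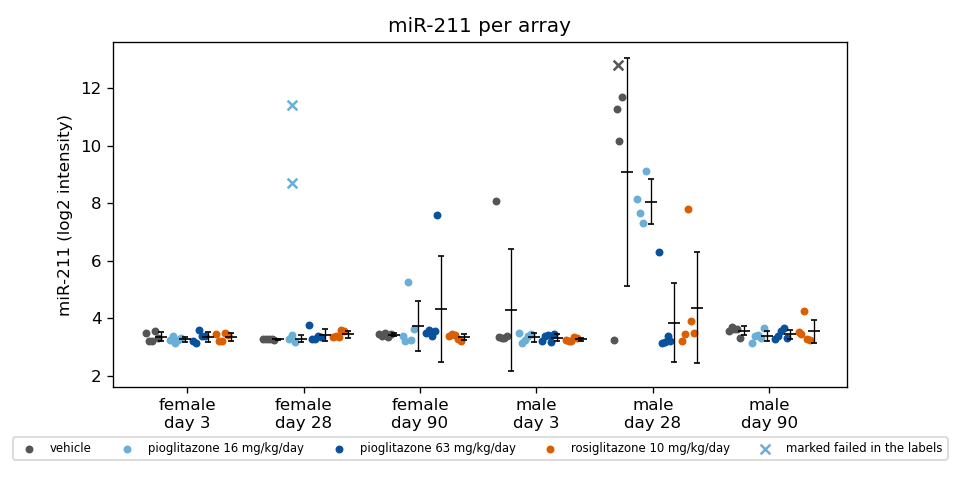
miR-211 (log2 intensity) in every array by sex, time and treatment, with the group mean and SD as bars and crosses for arrays the labels mark as failed. In males at day 28 the passing vehicle arrays lie between 3.22 and 11.67 and the pioglitazone 16 arrays between 7.31 and 9.10. The failed arrays are 1 vehicle male at day 28 (12.80) and 2 pioglitazone 16 females at day 28 (8.70 and 11.39).

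Averaged over the 6 sex and time combinations, 6 miRNAs were higher and 26 lower with pioglitazone 63 than with vehicle, with an unadjusted count of 66. Among those with the same direction in at least 5 of 6, the higher ones were miR-98 of the let-7 family (0.81, SE 0.26, adjusted p = 0.0287), miR-365 (0.70, SE 0.16, adjusted p = 0.00320), miR-186 (0.70), miR-352 (0.65) and miR-7a (0.55). The lower ones were let-7b* (-0.86), miR-207 (-0.72, SE 0.16, adjusted p = 0.00320) and let-7e* (-0.61). The rule counts direction, not size: let-7b* differed by -5.08 in males at day 28. In females at day 90 let-7b* (0.81), miR-207 (0.34) and let-7e* (0.66) were higher than in vehicle rats, without passing. Their means with pioglitazone 63 lay near the floor, at 3.49, 3.23 and 3.30. With rosiglitazone 1 miRNA was higher, miR-376b-3p (0.31), and 33 lower, with an unadjusted count of 56. With the same rule of 5 in 6, the lowest against vehicle were let-7d* (-1.11), miR-328a (adjusted p = 0.0403), miR-211 (-0.94), miR-3550 (-0.92) and miR-346 (-0.87, SE 0.18, adjusted p = 8.25e-04). Then came miR-487b* (-0.86), miR-207 (-0.78), miR-3563-5p (-0.78), let-7e* (-0.71) and miR-298 (-0.67). With rosiglitazone these averaged from 3.15 (miR-487b*) to 3.29 (miR-298), near the floor.

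Pioglitazone 16 gave 0 calls in limma (unadjusted count 29), with miR-181a (-0.86) and miR-22 (0.33) at the smallest p, and 33 calls without replicate 1 of the vehicle males at day 28 or 1 without its own female day-28 replicate 3. Without 1 vehicle male at day 28 the pioglitazone 63 count went to 55, 10, 21 or 8 (replicates 1, 3, 4 and 5), and without replicate 1 of the vehicle males at day 3 to 14. Without the male day-28 groups all 3 means gave 0 calls, and centred arrays gave 0 as well. With the array median as a covariate the split was 12 higher and 28 lower for pioglitazone 63 and 7 and 36 for rosiglitazone, for which quantile normalization gave 4 and 23. With the male day-28 arrays out of the fit too, 1 miRNA passed, miR-365 with pioglitazone 63 (0.65, adjusted p = 0.0453).

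miR-365 was higher with pioglitazone 63 in 5 of 6 combinations: females at day 3 (0.74), day 28 (0.46) and day 90 (1.29), and males at day 28 (0.92) and day 90 (0.81), against -0.04 in males at day 3. In females at day 90 it stood at 11.53 ± 0.25 with pioglitazone 63, 11.48 ± 0.34 with rosiglitazone and 10.25 ± 0.82 with vehicle (SD, n = 5 each). With the array median as a covariate its mean difference with pioglitazone 63 was 0.69 (adjusted p = 0.00268 in limma), whereas its call ended with centred arrays. Its mean difference was 0.42 with rosiglitazone (adjusted p = 0.0680) and 0.37 with pioglitazone 16, which did not pass. miR-193, described as sharing a locus with miR-365, differed by 0.11 (SE 0.40) with pioglitazone 63.

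**Figure D3:**
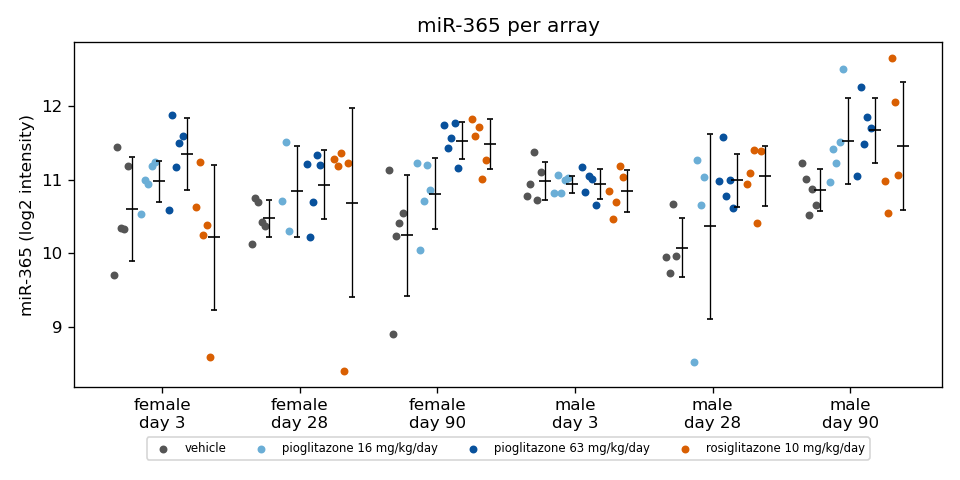
miR-365 (log2 intensity) in every passing array by sex, time and treatment, with the group mean and SD as bars. The pioglitazone 63 mean exceeds the vehicle mean in every combination but males at day 3, where they are 10.95 and 10.98.

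Of 42 tests of lists over the 3 mean effects, 2 passed with the preset correlation, and 0 with an estimated one. The Dlk1-Dio3 list was lower with pioglitazone 16 (median -0.14, adjusted p = 0.0363, or adjusted p = 0.953 with an estimated correlation), with 0 members called. The let-7 family was lower with rosiglitazone (median -0.26, adjusted p = 0.0280, or adjusted p = 0.953 with an estimated correlation). Its 5 called members were all minor strands (let-7a-1*, b*, d*, e* and f-1*), and both medians stayed negative in all 4 scalings. Neither list passed with centred arrays.

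Other lists did not pass. The muscle list median was 0.53 with pioglitazone 63, 0.10 with pioglitazone 16 and 0.15 with rosiglitazone. The corresponding medians were 0.05, 0.12 and 0.06 for epithelial miRNAs, 0.18, -0.13 and -0.12 for fibroblast, -0.37, -0.12 and -0.39 for red cell, and -0.12, -0.01 and -0.09 for leukocyte miRNAs. They were 0.11, -0.03 and 0.06 for inflammation, 0.04, 0.18 and 0.18 for neural, 0.28, 0.16 and 0.14 for miR-17-92, and 0.10, 0.14 and 0.05 for p53-responsive miRNAs. For adipocyte differentiation they were 0.01, -0.02 and -0.04, for Pparg-targeting miRNAs 0.24, 0.20 and -0.05, and for the miR-29 family 0.03, 0.26 and -0.21. Some scalings turned the sign of the adipocyte medians with pioglitazone 63 and rosiglitazone, the Pparg median with rosiglitazone, the neural median with pioglitazone 63 and the leukocyte median with pioglitazone 16. The Dlk1-Dio3 medians not given above were -0.05 with pioglitazone 63 and 0.04 with rosiglitazone, and the let-7 ones -0.24 with pioglitazone 16 and -0.17 with pioglitazone 63. The smallest adjusted p among all of these was 0.152, for muscle and Dlk1-Dio3 with pioglitazone 63 and epithelial with pioglitazone 16.

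Pioglitazone and rosiglitazone share a benzyl thiazolidinedione and differ in the other end, an ethylpyridine in pioglitazone and a pyridine on a methylated amine in rosiglitazone. Their doses differed, so the responses stand side by side and not at a matched dose. The test of the differences between the mean effects of the 3 treatments gave, in limma, 0 calls for the high against the low pioglitazone dose, for pioglitazone 63 against rosiglitazone and for pioglitazone 16 against rosiglitazone, with unadjusted counts of 12, 3 and 28. Pioglitazone 16 against rosiglitazone gave 17 calls with only the groups of the contrast, 9 with the failed arrays kept, 1 with the array median as a covariate and 2 without replicate 3 of the pioglitazone 16 males at day 28. The dose contrast gave 1 with only its groups or with the failed arrays kept. The median 95% interval of these differences reached 0.45, 0.44 and 0.45 to either side. For miR-365, pioglitazone 63 exceeded rosiglitazone by 0.28 (95% interval -0.03 to 0.58) and pioglitazone 16 by 0.32 (0.01 to 0.64).

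For miR-98 the difference between pioglitazone 63 and rosiglitazone was 0.35 (95% interval -0.15 to 0.86), for let-7d* 0.32 (-0.32 to 0.97), for miR-346 0.13 (-0.22 to 0.49) and for miR-207 0.06 (-0.25 to 0.38). miR-207 had the smallest p for the doses (-0.54) and for pioglitazone 16 against rosiglitazone (0.61), followed by miR-378 (0.86) and miR-702-3p (0.71). The dose difference in miR-207 became 0.03 without the male day-28 groups. For pioglitazone 63 against rosiglitazone, miR-376b-3p (-0.25) and miR-3562 (-0.19) came first (adjusted p = 0.991 each).

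Within single combinations, pioglitazone 63 against rosiglitazone called 0 miRNAs in each of 6. The high against the low pioglitazone dose called 27 in males at day 28 (3 higher, 24 lower), miR-376b-5p in females at day 28 (-0.89, adjusted p = 0.00172) and miR-144* in males at day 90 (-1.13, adjusted p = 0.0335). Pioglitazone 16 against rosiglitazone called 35 in males at day 28 (28 higher, 7 lower) and miR-431 in females at day 3 (-0.69, adjusted p = 0.0130). In females at day 28 it called miR-347 (-4.45, adjusted p = 0.00385) and miR-376b-5p (0.79, adjusted p = 0.00638). These single-combination tests were added after the values were seen.

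In the mean effects, 24 miRNAs were lower with both pioglitazone 63 and rosiglitazone and 0 higher with both. Independent lists of these sizes would share 2.85 lower miRNAs, but both effects use the same vehicle arrays, so these lists are not independent. Simulated unchanged groups shared 0, which decides nothing, since no miRNA differs there and few calls exist to share. Across miRNAs, which are not independent replicates, the mean effects correlated at 0.81 (simulated mean 0.53, 95% of draws from -0.02 to 0.85), with a covariance of 0.102 (simulated 0.0368). Effects of the 2 pioglitazone doses correlated at 0.72 (simulated 0.48, -0.14 to 0.87), and those of pioglitazone 16 and rosiglitazone at 0.66 (simulated 0.49, -0.15 to 0.87). All 3 correlations lay within the range of unchanged groups. The simulated groups lack the unequal spread of the real ones, such as the wide male day-28 vehicle group, so this range may not hold for them. With the vehicle arrays split between the compounds, pioglitazone 63 and rosiglitazone had 1 and 29 calls in one assignment and 20 and 0 in the other, too few to test sharing, and their effects correlated at 0.27 or 0.76. Without the male day-28 groups no calls were left to share, and the correlation was 0.53 with the same sign in 71.1% of miRNAs.

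The effect of pioglitazone 63 differed between the sexes in 34 miRNAs, 33 of them with a higher value of the effect in females, and that of rosiglitazone in 39, 38 of them higher in females. With pioglitazone 63 the female effect exceeded the male effect by 2.45 for miR-211, 2.34 for miR-328b-3p and 2.20 for let-7b*, and for miR-126 the difference was -1.80. With rosiglitazone the differences were 2.10 for miR-328b-3p, 2.07 for miR-702-3p, 2.04 for let-7b* and -2.14 for miR-126. Unadjusted counts were 61 and 62. Without the male day-28 groups, pioglitazone 63 gave 0 calls and rosiglitazone 5, all higher in females: miR-434 (1.99), miR-344a-3p (1.23), miR-138 (1.16), miR-411* (0.95) and miR-431 (0.58). With those arrays also out of the fit, or with centred arrays, both gave 0.

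With the array median as a covariate the split of calls for pioglitazone 63 was 37 higher and 19 lower, and for rosiglitazone 33 and 17 after quantile normalization. The pioglitazone 16 sex difference gave 0 calls in limma (unadjusted count 22), with miR-369-5p (0.79) and miR-376b-5p (0.39) first. It gave 19 with the failed arrays kept, 34 without replicate 1 of the vehicle males at day 28 and 1 without replicate 2 of its females at day 28. The differences between days 90 and 3 gave 0 calls each in limma, with unadjusted counts of 22 for pioglitazone 16, 12 for pioglitazone 63 and 23 for rosiglitazone. The smallest p belonged to miR-144* (0.84) and miR-664-2* (-0.63), to miR-181d (-1.72) and miR-30c-2* (-0.77), and to miR-598-5p (-0.63) and miR-365 (1.18). miR-181d with pioglitazone 63 passed with the male day-28 arrays out of the fit (adjusted p = 0.0131).

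Among vehicle rats, females exceeded males in 10 miRNAs and fell below them in 44 over the 3 times, with an unadjusted count of 80. miR-126 (1.79), miR-126* (1.08) and miR-7a (0.76) were higher in females, and miR-211 (-2.29), miR-328b-3p (-2.23) and let-7b* (-2.19) lower. At day 28 against day 3, 37 were higher, led by let-7b* (2.45), miR-211 (2.36) and miR-328b-3p (2.30), and 46 lower, led by miR-144 (-2.75), miR-126 (-2.70) and miR-199a-3p (-2.63), with an unadjusted count of 123. Without the male day-28 groups both contrasts gave 0 calls, the second then in females alone, where miR-211 differed by -0.08 and miR-199a-3p by 0.21. The split of sex calls was 27 higher and 52 lower with the array median as a covariate, or 20 and 44 after quantile normalization, and that of day-28 calls was 49 and 16 with centred arrays, 51 and 37 after quantile normalization and 48 and 33 with the covariate. The median of all miRNAs was 0.16 for sex and -0.28 for day 28, and with centred arrays 0.06 and 0.20.

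At day 90 against day 3, vehicle rats had 17 lower and 4 higher miRNAs, with an unadjusted count of 53. miR-127 (-2.31, SE 0.48, adjusted p = 0.00144) and miR-434 (-1.71, SE 0.40, adjusted p = 0.00711), both made from the Dlk1-Dio3 cluster, and the red cell miR-144 (-1.59) led the falls. miR-1949 (2.10, SE 0.55, adjusted p = 0.0135), miR-30c-2* (0.66) and miR-664-2* (0.51) led the rises. miR-127 went from 6.15 ± 1.60 to 4.49 ± 0.84 in females and from 6.84 ± 1.65 to 3.87 ± 0.45 in males (SD, n = 5 each).

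Of the 27 Dlk1-Dio3 miRNAs, 13 fell between days 3 and 90 and 0 rose in vehicle rats, among them miR-379 (-1.40), miR-337 (-1.09) and miR-411 (-1.07). Adjusted over the list alone, 17 fell and 2 rose. The median was -0.71 (adjusted p = 5.88e-11 with the preset correlation, adjusted p = 0.114 with an estimated one). It was -1.10 in males (16 falls, adjusted p = 0.0192 with an estimated correlation) and -0.21 in females (0 falls, adjusted p = 0.215), and the difference between the sexes was not tested. By fry the adjusted p was 1.97e-04 in males and 0.317 in females. The values by sex are adjusted over tests of this list alone, unlike the adjusted p = 0.114 over both sexes, so they do not compare directly. The median was -0.72 with centred arrays, -0.58 after quantile normalization and -0.71 with the array median as a covariate. Epithelial miRNAs had a median of 0.50, fibroblast miRNAs of -0.78 and the 3 red cell miRNAs of -1.59, and none of these lists passed (adjusted p = 0.0811, 0.410 and 0.106). Of the red cell miRNAs 1 fell, or 2 adjusted over the list alone.

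The 21 calls at day 90 fell to 3 (miR-127, miR-434 and miR-1949) without replicate 3 of the vehicle males at day 3, and to 7 or 13 without replicate 2 or 5 of the vehicle females at day 3. Centred arrays left the same 3, only the brighter miRNAs or only the groups of the contrast left 1, and the array median as a covariate gave 12 higher and 22 lower.

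**Figure D4:**
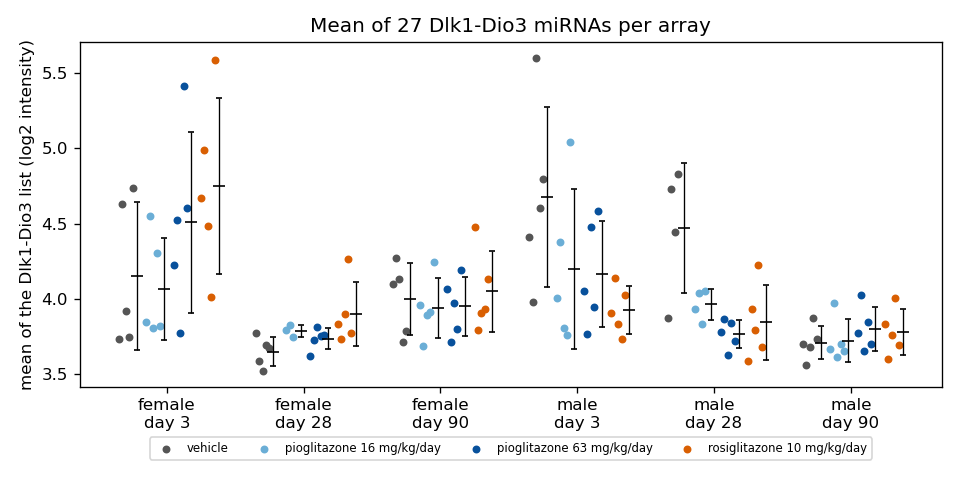
Mean log2 intensity of the 27 Dlk1-Dio3 miRNAs in every passing array by sex, time and treatment, with the group mean and SD as bars. Vehicle males average 4.68 at day 3 and 3.71 at day 90, vehicle females 4.15 and 4.00, and rosiglitazone females 4.75 and 4.05.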

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

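Chosen after the result was seen were the tests of the male day-28 calls, of miR-365 against the male day-28 arrays and against muscle content, of miR-193, of the Dlk1-Dio3 list with a fibroblast covariate, the fits without the male day-28 groups or arrays, and day 90 against day 3 in treated rats. Leaving out single arrays and the counts of splits were set up before the data were examined.

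In 9 of 43 tests, each of 1 group for the array median or for a named miRNA, 1 array stood apart from the others by the size of its gap, where chance gives about 1 in 20. For the array median these were vehicle females at day 90, replicate 2 (3.703), pioglitazone 16 females at day 3, replicate 5 (4.89), pioglitazone 16 males at day 90, replicate 5 (3.81), and pioglitazone 63 females at day 28, replicate 2 (3.80). The same held for pioglitazone 63 females at day 90, replicate 5 (5.12), rosiglitazone females at day 90, replicate 3 (3.80), and rosiglitazone males at day 90, replicate 3 (3.80). For miR-211 they were pioglitazone 63 males at day 28, replicate 1 (6.30), and rosiglitazone males at day 28, replicate 3 (7.79).

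The effects of pioglitazone 63 and rosiglitazone differed between the sexes in 34 and 39 miRNAs, but in 0 and 5 without the male day-28 groups, and in 0 each with those arrays out of the fit or with centred arrays. Female minus male, pioglitazone 63 gave 2.45 for miR-211, 2.34 for miR-328b-3p, 2.20 for let-7b* and -1.80 for miR-126. Rosiglitazone gave 2.10 for miR-328b-3p, 2.07 for miR-702-3p, 2.04 for let-7b* and -2.14 for miR-126. In the arrays that the labels mark as failed, used here only in the alternative that keeps them and in the correlation given below, miR-211 was 12.80 in vehicle males at day 28, replicate 2. It was 8.70 and 11.39 in pioglitazone 16 females at day 28, replicates 1 and 5, against a mean of 4.34 over all passing vehicle arrays. Passing arrays of the same groups averaged 9.08 in vehicle males at day 28 and 3.29 in pioglitazone 16 females at day 28.

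Most treatment calls lay in males at day 28, where miR-211, let-7b* and miR-328b-3p were high in vehicle rats and low with pioglitazone 63 and rosiglitazone. An effect of those treatments stays open: one that prevented a change of vehicle males would leave treated males like their own other days. Males of the 2 treatments differed from their own days 3 and 90 in at most 1 miRNA, whereas vehicle males differed in 156. This argues only against treated males having moved away from their own other days. The same comparison in females gave 20 calls with rosiglitazone, 1 with pioglitazone 16 and 0 with pioglitazone 63 or vehicle. Array brightness is argued against, since pioglitazone 63 gave 101 calls with the array median as a covariate, beside 112 without it. Array quality of the vehicle group is a candidate explanation: across miRNAs, its displacement from days 3 and 90 correlated at 0.702 with that of the failed arrays from the passing arrays of pioglitazone 16 females at day 28. A biological change in vehicle and pioglitazone 16 males at day 28 stays open, untested, and no batch was given.

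miR-365 was higher with pioglitazone 63 by 0.70 (95% interval 0.39 to 1.01, adjusted p = 0.00320). The male day-28 arrays as the whole cause are argued against, since without these groups the difference was 0.652 (0.32 to 0.99). The call ended there at adjusted p = 0.0606 with fewer arrays in the contrast, and adjusted p was 0.0453 with those arrays out of the fit. With the muscle list mean as a covariate it was 0.630 (0.33 to 0.93), so adjusting for that mean left most of the difference. Muscle content itself stays open, since the list mean may correct for it only in part. A compound effect on the gene pair of miR-193 and miR-365 stays open, since miR-193 differed by 0.115 with an interval from -0.68 to 0.91.

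The mean of the Dlk1-Dio3 list was lower in treated than in vehicle males at day 3 by a mean difference of -0.580 (95% interval -0.91 to -0.25). With the fibroblast list mean as a covariate it was -0.484 (-0.79 to -0.18), so adjusting for that mean left most of the difference. Fibroblast content itself stays open. The list mean on the deposited scale also carries array brightness, and it may correct for content only in part. A single vehicle array stays open: without replicate 3 the difference was -0.350 (-0.69 to -0.01), and without any other of the 5 it was between -0.551 and -0.755. A compound effect may lie behind part of it, which these 5 vehicle rats do not decide.

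For every contrast the same arrays were split into its groups in other ways, and each count of splits includes the real one. For the 0-call contrasts all 100 of 100 splits gave as many calls, which any split does and which decides nothing. The highest other counts were 11, 2, 31 and 1 for pioglitazone 16 in females at days 3 and 90 and males at days 3 and 90, and 48, 0, 17 and 0 for pioglitazone 63 in females at days 3 and 28 and males at days 3 and 90. They were 16, 3, 6 and 2 for rosiglitazone in females at days 3, 28 and 90 and males at day 90. For the pioglitazone 16 mean the highest was 30, for the differences between treatments 8, 4 and 41, for the pioglitazone 16 sex difference 56, and for the day differences 1, 30 and 6. In some contrasts other splits gave 30 or more calls beside a real count of 0, and the cause of this was not tested.

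Chance was not excluded for pioglitazone 16 in females at day 28 (8 of 56 splits, real count 1, highest other 2) or males at day 28 (6 of 35, real 38, highest other 110). Nor was it for pioglitazone 63 in females at day 90 (5 of 100, real 1, highest other 2) or rosiglitazone in males at day 28 (8 of 100, real 74, highest other 133). Under 5 of 100 splits, the limit set beforehand, reached the real count for pioglitazone 63 in males at day 28 (3 of 100, real 112, highest other 125) and rosiglitazone in males at day 3 (4 of 100, real 11, highest other 16). The same held for the pioglitazone 63 mean (4 of 100, real 32, highest other 79), the rosiglitazone mean (2 of 100, real 34, highest other 101), and their sex differences (4 of 100, real 34, and 2 of 100, real 39, highest other 41 in both). Among vehicle rats it held for sex (4 of 100, real 54, highest other 66), day 28 (4 of 100, real 83, highest other 141) and day 90 (1 of 100, the real split alone, real 21, highest other 3). For day 90 against day 3 in treated rats it held too (1 of 100, the real split alone, real 34, highest other 19). These shares are not adjusted over the contrasts tested, so they do not by themselves exclude chance. Some splits gave 2 or more times the real count, as in both means, and the cause of this was not tested.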

How the results depend on the processing

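Chosen after the data were seen were the fits without the male day-28 groups, with the male day-28 arrays also out of the fit, with quantile normalization, with the array median or the muscle or fibroblast list mean as a covariate, and the contrast of day 90 with day 3 in treated rats. Over all alternatives apart from left-out arrays, named miRNAs gave 606 of 823 values with the same direction and side of the threshold, 193 no longer past it, 16 newly past it and 8 reversed. Tested lists gave 254 of 285, with 7, 5 and 19. The cause of each change below was not tested, except that the contrasts without the male day-28 groups, the brighter miRNAs and the left-out arrays rest on fewer arrays or miRNAs. Values near the floor limit what a low miRNA can show.

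With failed arrays kept, the count of calls was 20 for pioglitazone 16 females day 28 (1 without them), 0 for pioglitazone 63 females day 90, 7 for rosiglitazone males day 3, 17 for the pioglitazone 63 mean, 1 for the pioglitazone doses, 9 for pioglitazone 16 against rosiglitazone and 19 for the pioglitazone 16 sex difference. The muscle list median with pioglitazone 16 was then -0.10 and the adipocyte median with rosiglitazone 0.039.

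With centred arrays the count was 0 for pioglitazone 16 females day 28, pioglitazone 63 females day 90, the pioglitazone 63 and rosiglitazone means and both their sex differences, 1 for rosiglitazone males day 3, 3 for vehicle day 90, 17 for treated day 90 and 0 for list shifts. The adipocyte medians were -0.024 with pioglitazone 63 and 0.018 with rosiglitazone, and the Pparg median with rosiglitazone 0.0033.

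With brighter miRNAs only the count was 0 for pioglitazone 16 females day 28, pioglitazone 63 females day 90, rosiglitazone males day 3, the rosiglitazone mean, both sex differences and list shifts. The miRNAs called in the first 2, miR-376b-5p and miR-328a*, are too dim to be among those tested. It was 10, 72 and 22 for pioglitazone 16, pioglitazone 63 and rosiglitazone males day 28, 1 for the pioglitazone 63 mean, 6 for vehicle sex, 18 for vehicle day 28, 1 for vehicle day 90 and 12 for treated day 90. Muscle medians were -0.10 with pioglitazone 16 and -0.12 with rosiglitazone, and with rosiglitazone the inflammation median was -0.046 and the p53 median -0.081.

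With the replicate block the count was 13 for pioglitazone 16 males day 28 and 0 for pioglitazone 63 females day 90, the muscle median with pioglitazone 16 was -0.047, and no other count of miRNAs moved by over 1.5 times. With this replicate block 3 lists passed, the 2 passing without it and the epithelial list with pioglitazone 16 (adjusted p = 0.0314), all at the preset correlation. At an estimated one 0 lists passed with this block (smallest adjusted p = 0.954). Averaged over all groups the numbers did not pair the samples: the mean same-number correlation was 0.043 against 0.0023 for other numbers. In 2 of 36 pairs of groups every same-number correlation was above 0.1. One of these pairs is vehicle and pioglitazone 63 females at day 90 (lowest 0.189, mean 0.286 against -0.065), the comparison with the miR-328a* call, which ended with the block at adjusted p = 0.0533. The other is pioglitazone 16 and rosiglitazone females at day 28 (3 same-number pairs, lowest 0.233, mean 0.310 against -0.073). Calls between those groups were not fitted with the block. In females at day 90 the mean same-number correlation of each pair of groups lay between 0.171 and 0.398. For other numbers it lay there between -0.065 and 0.043. Single same-number values fell as low as -0.450, yet a factor shared by replicate number is not excluded in those females. The replicate block was not estimable for the vehicle and treated time and vehicle sex contrasts.

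Without the male day-28 groups the count was 0 for the pioglitazone 63 and rosiglitazone means, the pioglitazone 63 sex difference, vehicle sex and vehicle day 28, 5 for the rosiglitazone sex difference, 4 for list shifts and 0 for the overlap between compounds, which had no calls left to share. The 4 lists were miR-29 with pioglitazone 16, red cell and leukocyte with pioglitazone 63, and let-7 with rosiglitazone, all at the preset correlation. At an estimated one only the leukocyte list passed there (adjusted p = 0.0450). miR-207 was 0.027 between the pioglitazone doses, miR-376b-5p -0.038 for the pioglitazone 16 sex difference, miR-211 -0.083 and miR-199a-3p 0.21 for vehicle day 28. List medians were -0.037 for miR-17-92 with pioglitazone 16. With pioglitazone 63 they were -0.033 for epithelial, -0.12 for inflammation and -0.0065 for adipocyte, and with rosiglitazone -0.055 for muscle, -0.091 for inflammation, -0.022 for miR-17-92, 0.058 for adipocyte and 0.10 for Pparg.

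With the male day-28 arrays out of the fit these 4 miRNAs had the same values. The count was 1 for the pioglitazone 63 mean, 0 for the rosiglitazone mean, both sex differences, vehicle sex and vehicle day 28, 1 for pioglitazone 16 males day 90, 2 for rosiglitazone females day 28 and 1 for the pioglitazone 63 day difference. With the array median as a covariate it was 2, 1 and 4 for pioglitazone 16 females day 28, females day 90 and males day 90, 2, 17 and 1 for rosiglitazone females day 28, males day 3 and males day 90, 1 for pioglitazone 16 against rosiglitazone, 56 for the pioglitazone 63 sex difference and 34 for vehicle day 90. With quantile normalization it was 0 for pioglitazone 16 females day 28 and rosiglitazone males day 3, 1 for pioglitazone 16 females day 90 and pioglitazone 63 females day 3, and 11 for vehicle day 90.

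With only the groups of the contrast the count was 0 for pioglitazone 16 females and males day 28, pioglitazone 63 females day 90 and rosiglitazone males day 3 and day 28, and 1 for rosiglitazone females day 28. It was 3 for the pioglitazone 63 mean, 1 for the pioglitazone doses, 17 for pioglitazone 16 against rosiglitazone, 49 for vehicle day 28 and 1 for vehicle day 90. With an estimated correlation 0 lists passed, and with the vehicle arrays split the overlap was 0 in both assignments, where one compound had only 1 or 0 calls, so that little or nothing could be shared.

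Each array was left out in turn, which leaves at least 2 in a group. For pioglitazone 16 females day 28 the count ran from 1 to 11 (11 and 2 without treated replicates 2 and 4), for females day 90 from 0 to 3 (3 without vehicle replicate 1, 1 without treated replicate 2), for males day 3 from 0 to 7 (2 without vehicle replicate 1, 7 without treated replicate 5) and for males day 28 from 0 to 79 (79, 0, 8 and 1 without vehicle replicates 1, 3, 4 and 5, 19 and 10 without treated replicates 2 and 3). Its mean ran from 0 to 33 (33 without replicate 1 of the vehicle males at day 28, 1 without treated female day-28 replicate 3) and its sex difference from 0 to 34 (34 without the same vehicle array, 1 without treated female day-28 replicate 2).

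For pioglitazone 63 females day 3 the count ran from 0 to 4 (4 without treated replicate 3), females day 90 from 0 to 3 (3 without vehicle replicate 1, 0 without vehicle replicates 2 and 3 or treated replicates 1, 2, 3 and 5), males day 3 from 0 to 3 (3 and 1 without vehicle replicates 2 and 5) and males day 28 from 68 to 136 (72 and 68 without vehicle replicates 3 and 5). Its mean ran from 8 to 55 (55, 10, 21 and 8 without replicates 1, 3, 4 and 5 of the vehicle males at day 28, 14 without replicate 1 of the vehicle males at day 3) and its sex difference from 32 to 53 (53 without replicate 1 of the vehicle males at day 28).

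For rosiglitazone females day 3 the count ran from 0 to 3 (3 without vehicle replicate 5, 1 without treated replicate 3 or 4), females day 28 from 0 to 4 (2, 2, 4 and 3 without treated replicates 1, 2, 3 and 5), females day 90 from 0 to 1 (1 without vehicle replicate 1) and males day 3 from 0 to 21 (21 and 0 without vehicle replicates 2 and 3, 6, 4 and 5 without treated replicates 1, 3 and 4). Its day difference ran from 0 to 1 (1 without treated male day-3 replicate 3), and pioglitazone 16 against rosiglitazone from 0 to 2 (2 without pioglitazone 16 male day-28 replicate 3). Vehicle day 90 ran from 3 to 29 (7 and 13 without female day-3 replicates 2 and 5, 3 without male day-3 replicate 3). No left-out array moved the counts of rosiglitazone males day 28 (57 to 107), its mean (26 to 48) and sex difference (36 to 48), vehicle sex (44 to 79), vehicle day 28 (61 to 117) or treated day 90 (28 to 38) by over 1.5 times.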

Other observations

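The contrast of day 90 with day 3 in treated rats and its list tests were chosen after the vehicle result was seen, and so were the correlations below. In treated rats, averaged over the 3 treatments and both sexes, 27 miRNAs fell and 7 rose between days 3 and 90 (unadjusted count 61). The falls were led by miR-127 of the Dlk1-Dio3 cluster (-1.90, SE 0.28, adjusted p = 8.38e-08), miR-181c (-1.65, SE 0.23, adjusted p = 6.06e-08) and miR-379, also of that cluster (-1.38). miR-181d (-1.26) and miR-181b (-0.85), let-7c (-0.59) and let-7b (-0.49) fell too. The rises were led by miR-1949 (1.15, SE 0.32, adjusted p = 0.00781), miR-365 (0.53), and miR-29a (0.50), a regulator of collagen transcripts.

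Of the 27 Dlk1-Dio3 miRNAs, 13 fell and 0 rose in treated rats (16 fell adjusted over the list alone), and 22 had a negative difference. The list median was -0.25 (adjusted p = 3.12e-08 with the preset correlation, adjusted p = 0.0825 with an estimated one), and -0.09 with centred arrays. The miR-29 family had a median of 0.50 (adjusted p = 6.62e-04, or adjusted p = 0.0825 with an estimated correlation), positive in all 4 scalings. By fry the adjusted p was 1.53e-04 for the Dlk1-Dio3 list and 0.00222 for the miR-29 family. Of the 17 miRNAs lower in vehicle rats and the 27 lower in treated rats, 13 were shared, where independent lists would share 1.52. These lists are not independent: 13 miRNAs of each belong to the Dlk1-Dio3 cluster, and both contrasts use the same variance per miRNA. The overlap is therefore not a test of sharing. Without replicate 3 of the vehicle males at day 3, or with centred arrays, only 2 miRNAs were lower in vehicle rats, so at most 2 could then be shared. The vehicle and treated contrasts use different arrays, so no vehicle array enters both. The median of all miRNAs was -0.03, and 0.13 with centred arrays. The split of treated calls was 9 higher and 8 lower with centred arrays, 9 and 16 after quantile normalization, and 21 and 30 with the array median as a covariate.

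By sex, the Dlk1-Dio3 median between days 3 and 90 was -0.73 in rosiglitazone females (7 falls, adjusted p = 0.00740 with an estimated correlation) and -0.43 in pioglitazone 63 females (5 falls, adjusted p = 0.0812). It was -0.05 in pioglitazone 16 females, and -0.40, -0.55 and -0.12 in pioglitazone 16, pioglitazone 63 and rosiglitazone males, with 0 falls in each. By fry the adjusted p was 0.00238 in rosiglitazone females, 0.0228 in pioglitazone 63 females and from 0.0894 to 0.581 in the other groups. All p-values by sex are adjusted over tests of the Dlk1-Dio3 list alone. Differences between these medians were not tested.

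Over the 116 arrays, as deviations from group means, the epithelial list mean correlated with the Dlk1-Dio3 mean at r = -0.635 (rho -0.658, adjusted permutation p = 6e-05) and with the muscle mean at r = -0.473 (rho -0.465, adjusted p = 6e-05). It correlated with the fibroblast mean at r = -0.266 (rho -0.307, adjusted p = 0.0285). With the endothelial mean r was 0.250 (adjusted p = 0.0285), but rho was 0.139 with permutation p = 0.170, and with red cell (0.132, adjusted p = 0.267) and leukocyte means (0.061, adjusted p = 0.591) it did not pass. Without the 2 farthest arrays the first 3 were -0.620, -0.460 and -0.259, and the endothelial one 0.223. These were 6 relations with 100000 permutations, whose smallest possible p is 1e-05. With array medians subtracted, r was -0.736 for muscle, -0.760 for fibroblast, -0.118 for Dlk1-Dio3 (adjusted p = 0.322) and 0.124 for endothelial (adjusted p = 0.322).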
